A study of Mus musculus with 6 samples.

How the data were processed

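RNA was profiled in 6 libraries of basal cells sorted from mouse esophageal epithelium, 3 labelled Krt15-negative and 3 labelled Krt15-positive. Per the labels' protocols, the mice carried a Krt15 promoter-driven, RU486-inducible Cre recombinase (Krt15-CrePR1) and a membrane Tomato/GFP reporter, received 1 mg of RU486 (mifepristone), and were sampled 24 h later. Cells with high CD29 (integrin beta-1) were separated by GFP, which marks cells in which the Krt15 promoter had driven recombination. Per the labels' protocols, cDNA was made directly from the cells with a SMART-Seq v4 ultra-low-input kit and no separate RNA extraction. This chemistry does not mark strand, so reads from overlapping antisense genes cannot be told apart.

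The deposited table holds one value per gene and library for 24043 rows. The values are FPKM as the authors estimated them, that is fragments normalized to the length of the transcript in kilobases and to M mapped fragments (M, mega). The table's own title calls them counts, but the values contradict that. They are not whole. Among genes with a single annotated transcript and 1 FPKM or more, the median fell from 185 below 1000 bp to 8.77 above 4000 bp in the Krt15-negative replicate 1 library, and fell likewise in the other 5. Per the submitters' processing notes, STAR 2.5, Cufflinks 2.2.1, DESeq2 and the mm9 build were used, with no role or order given. The gene annotation, read filters and strand setting are not given in the sources used here. Because FPKM divides by an estimated transcript length and lets reads be shared between isoforms and near-identical genes, values of paralogs such as ribosomal protein genes are uncertain. An exact 0 can also be a failed estimate: Krtdap was listed at 0 in the Krt15-negative replicate 3 library and between 7254 and 41287 FPKM in the others, and 3 of 16 genes that every cell uses were listed at 0 in each of the Krt15-negative replicate 1 and 2 libraries. Values of genes listed at 0 are therefore given per library.

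Gene symbols that a spreadsheet had turned into dates (27 rows) were left out, which left 24016 genes. No coordinates are given, since the build named in the notes differs from that of the annotation at hand, which served for symbols and transcript lengths only. All 6 value columns carry the sample names of the labels, and no other column of per-sample values was present.

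Depth was estimated from the values. In 6640 genes with a single annotated transcript of at least 1500 bp, FPKM times length in kilobases piled up at a single-fragment step and again at 2 steps (within 7%), with few genes between. The inverse of that step gives 28, 41 and 39.4 M fragments for Krt15-negative replicates 1 to 3, and 26.9, 33.5 and 29.5 M for the Krt15-positive ones. These are approximate, because the authors' effective lengths are not known. No counting intervals are given.

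Values were analysed as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 libraries (9423) were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend (limma-trend), group as the only term and all 6 libraries in the fit. P-values were adjusted by the Benjamini-Hochberg method and called below 0.05. The design fixed beforehand named a count model for counts and this limma fit for normalized values, and the latter applied. Fold changes on this scale understate changes of low genes. The labels do not say that the libraries of a group came from separate animals. The limma p-values thus measure the spread between these libraries, which may be technical in part.

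Before the data were examined, 31 gene lists were fixed, covering basal and suprabasal keratinocytes, stem and progenitor markers, cell cycle, DNA repair, signalling, metabolism, stress, matrix, adhesion and markers of other cell types. Of their 909 symbols, 10 were matched through a RefSeq synonym and 3 had no row. The 26 lists with at least 5 measured members were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and with the variance trend, 2-sided. At the preset correlation its p-values rest mainly on the spread between genes and not on that between libraries. Camera with an estimated correlation and fry were also run. Camera compares the mean test statistic of a list's members with that of the other genes, so its direction can differ from that of the list mean. The median difference of all genes was 0.63. In 9 lists camera pointed down while the list mean was above 0, and none of these passed the test. Lists of further fibroblast genes, airway secretory genes, alveolar genes and 16 genes that every cell uses were written after the data had been opened. The mean over a list per library was compared by an exact permutation test, which with 3 libraries against 3 cannot go below p = 0.10.

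The rule for named genes was also fixed beforehand. It took Krt15, Itgb1, Krt5, Krt14 and Trp63; up to 12 genes of largest change past the threshold and alike in all 3 same-numbered pairs in each direction or, where fewer than 5 passed, the 5 of smallest p with an average log2 value of at least 3 (written for log2 CPM and applied to log2(FPKM + 1)); up to 4 members of smallest p of each list that passed its test or held a passing member; and the 2 most abundant members of each list of another cell type.

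Alternatives changed the scaling between libraries, the pseudocount (0.1 and 5), the filter (none, or 10 FPKM in all 3 libraries of a group), the null fold (1.5), the replicate number as a block, and the libraries left out (9 settings). Added after seeing the data were quantile normalization, genes at 1 FPKM or more in all 6 libraries, library weights, robust variance moderation, camera without the trend, the blocked camera with an estimated correlation, and the matrix list without fibroblast markers. The planned count tests were not run because the values are not counts. The comparison was tested on simulated data drawn from the real gene means and spreads (8738 genes passing the filter), with 50 genes changed at each size. Only genes with an average log2 value of at least 3 were changed, so lower genes are not covered. Genes were drawn as independent normal values, without correlation between genes or failed estimates at 0. The share called was 2% at a log2 change of 2, 12% at 3, 36% at 5 and 68% at 7, with 0 unchanged genes called.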

Results

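The study compared the transcriptomes of Krt15-positive and Krt15-negative basal cells of the mouse esophagus. These group names refer to GFP and not to the level of Krt15, since cells without recombination stay GFP-negative. Keratin 15 is an intermediate filament protein of basal keratinocytes. Each group held 3 libraries. Between 3247 and 9194 genes reached 1 FPKM per library. The Krt15-negative libraries had 3247, 6906 and 7934 such genes (mean 6029 ± 2464, SD, n = 3) and the Krt15-positive ones 8466, 9194 and 7072 (8244 ± 1078, SD, n = 3), a difference within the replicate spread (exact 2-sided permutation p = 0.20). The Krt15-negative replicate 1 library stood apart, with 3247 genes from an estimated 28 M fragments (M, mega), while the Krt15-positive replicate 1 library gave 8466 genes from an estimated 26.9 M.

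**Figure D1:**
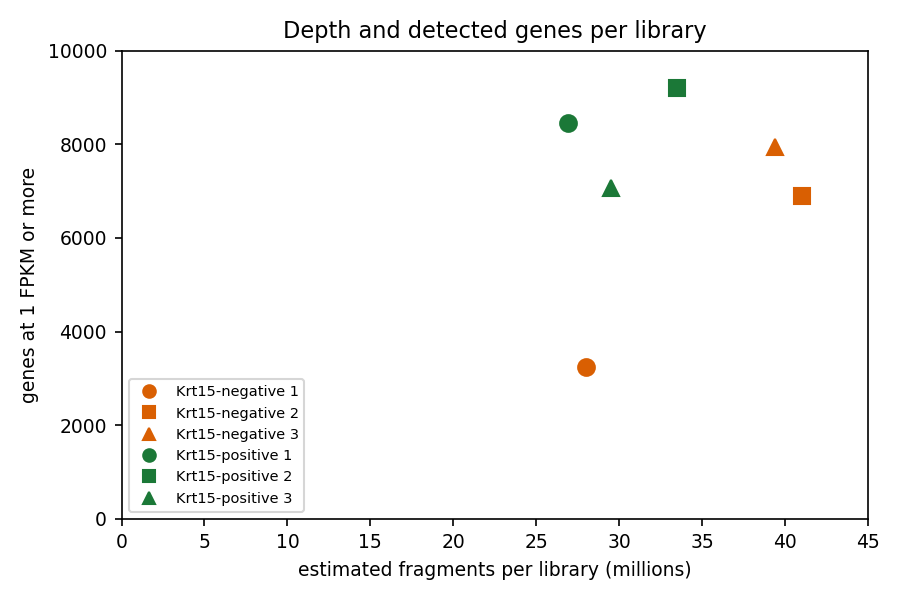
Genes at 1 FPKM or more (vertical axis) against the estimated number of sequenced fragments in M (horizontal axis), one point per library, colored by group and shaped by replicate number. The Krt15-negative replicate 1 library, at 3247 genes and 28 M fragments, lies below the others, which hold 6906 to 9194 genes.

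All 6 libraries expressed the keratins of basal esophageal cells at high level, and Krt15, whose promoter drives the Cre behind the sort, showed no difference past the test. Krt4 and Krt13 of the suprabasal list, named after their values were seen, were abundant too. They stood at 606 to 6295 and 847 to 3771 FPKM, each above Krt5 in every library. Krt15 stood at 2350, 6784 and 3412 FPKM in the Krt15-negative libraries and at 3350, 9692 and 2420 FPKM in the Krt15-positive ones (4182 ± 2315 and 5154 ± 3958, SD, n = 3). The difference, Krt15-positive minus Krt15-negative, was 0.18 on the log2(FPKM + 1) scale (SE 0.48, 95% CI -0.87 to 1.22, limma adjusted p = 0.93), and it turned to -0.29 with upper-quartile scaling. For Krt15 expression the difference also turned to -0.41 without the Krt15-positive replicate 2 library and to -0.17 without the Krt15-negative replicate 1 library. The basal keratins Krt5 (0.05, SE 0.57) and Krt14 (0.02, SE 0.47) had differences near 0, with upper-quartile values of -0.41 and -0.45. Trp63, the transcription factor of stratified epithelial progenitors, was 2.11 higher (SE 1.32, limma adjusted p = 0.79) and Itgb1, which encodes CD29, 1.34 higher (SE 1.24, limma adjusted p = 0.79). Both estimates lay within the replicate spread, and without the Krt15-negative replicate 1 library, where Trp63 was at 0.46 FPKM, the differences were 0.58 for Trp63 and 0.25 for Itgb1.

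**Figure D2:**
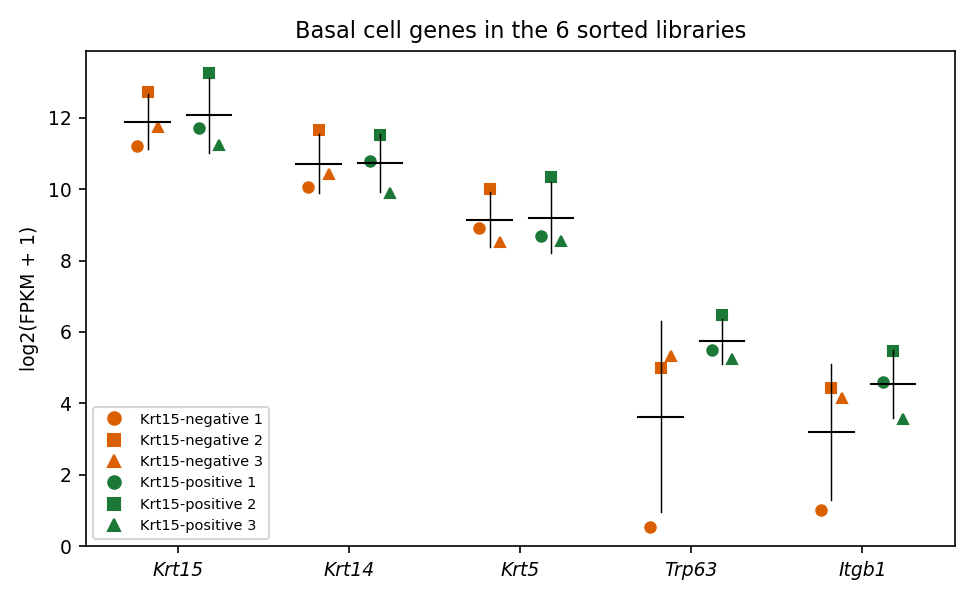
Expression of 5 basal cell genes as log2(FPKM + 1), one point per library, colored by group and shaped by replicate number, with horizontal bars at the group mean and vertical bars of 1 SD (n = 3). Krt15, Krt14 and Krt5 overlap between the groups, and the low Trp63 and Itgb1 points belong to the Krt15-negative replicate 1 library.

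Across all genes, the main comparison called 0 of 9423 genes at an adjusted p below 0.05 with limma, the smallest adjusted p being 0.40. At an unadjusted p below 0.05 there were 370 genes, 300 higher and 70 lower in Krt15-positive cells, where chance alone gives about 471. Quantile normalization gave 121 higher and 178 lower, median-of-ratios scaling 373 and 49, and leaving out the Krt15-negative replicate 1 library 170 and 154. The median difference of all genes, 0.63, was 0.73 with median-of-ratios scaling, 0.48 with upper-quartile scaling and 0.04 with quantile normalization. It was 0.03 without the Krt15-negative replicate 1 library and -0.10 among genes at 1 FPKM or more in all 6 libraries. Complete separation of the groups was seen for 11.3% of genes, where chance gives 10%, with 834 genes (8.85%) higher and 230 (2.44%) lower in Krt15-positive libraries. Tests with a stricter filter or with library weights called 10 and 8 genes, and 4 genes were shared by both: Rarres2, Fxyd1, Mfap5 and Dpt, all lower in Krt15-positive cells. Among the higher genes called with the stricter filter, which favors genes absent from one group, were Snora70, a small nucleolar RNA, Gadd45a, a growth-arrest gene, Ovol2, an epithelial transcription factor, and Orc5, of the origin recognition complex. These 4 are named after their values were seen, and each stood at no more than 0.60 FPKM in the Krt15-negative libraries and at 10.4 or more in the Krt15-positive ones. Leaving out the Krt15-negative replicate 2 library gave 1 gene, Saa3, a serum amyloid protein of the acute phase, named here after its values were seen. It stood at 1053, 0.059 and 1320 FPKM in the Krt15-negative libraries and at most 0.24 in the Krt15-positive ones.

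Among genes with an average log2 value of at least 3, the 5 of smallest p on the lower side were Rarres2, Fxyd1, Igfbp6, Mgp and Vim, and none passed the threshold. Rarres2, which encodes the chemoattractant chemerin, stood at 164, 52.4 and 262 FPKM in the Krt15-negative libraries, was listed at 0 in Krt15-positive replicates 1 and 3 and was below 0.001 FPKM in the other one (limma adjusted p = 0.40). Fxyd1, a regulator of the sodium pump, stood at 144, 34.4 and 62 FPKM against 0 in all 3 Krt15-positive libraries (limma adjusted p = 0.58). Mgp, matrix Gla protein, stood at 341, 21.8 and 47.8 FPKM against at most 0.075. Igfbp6, an IGF-binding protein, stood at 65.2, 75 and 162 FPKM against 0, 4.04 and 0.055. Vim, the intermediate filament of mesenchymal cells, stood at 72.5, 43.2 and 35.5 FPKM against 0, 3.5 and 0.074. On the higher side, with the same limit, the 5 genes were Bnip3, a mitophagy receptor, Qars, glutaminyl-tRNA synthetase, Dnajc4, a J-domain protein, Cnot8, a deadenylase subunit, and l7Rn6. Their differences were between 3.57 and 4.54 (limma adjusted p = 0.79 for each), and each was listed at 0 in Krt15-negative replicate 2 and at 2.07 FPKM or less in replicate 1. Bnip3 stood at 0.020, 0 and 7.91 FPKM against 34.2, 36.8 and 28.5. In Krt15-negative replicate 3 Dnajc4 stood at 62.5 FPKM, against 82.4, 77.6 and 133 in the Krt15-positive libraries. There l7Rn6 stood at 61 FPKM against 95.9, 93.5 and 78.6, Qars at 11.5 against 25.7, 24.55 and 60.1, and Cnot8 at 7.02 against 36.1, 66.7 and 15.2. With library weights the differences were 2.63 for Bnip3, 2.16 for Qars, 1.82 for Dnajc4, 1.84 for l7Rn6 and 2.77 for Cnot8.

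Of the 26 lists tested, 6 passed, and all 6 lay lower in Krt15-positive cells relative to other genes. These calls rest on the preset correlation, and no list passed with an estimated correlation or with fry. Other splits of the same 6 libraries called 3 to 8 lists, so the number called does not set the real groups apart. Of these 6 lists, that of fibroblast markers had the largest mean difference. Its mean over 15 measured members was 3.68 ± 1.01 in the Krt15-negative libraries and 1.11 ± 0.27 in the Krt15-positive ones (log2(FPKM + 1), SD, n = 3), with no overlap. The exact 2-sided permutation p was 0.10, the smallest that 3 libraries against 3 allow. Of the 15 members, 14 had a difference below 0 (camera adjusted p = 5.40e-18), and the adjusted p = 0.19 with an estimated correlation. No member passed over all genes. Adjusted over the list alone, 4 were lower: the microfibril protein gene Mfap5, the matrix protein gene Dpt (dermatopontin), Vim and the collagen gene Col3a1. Mfap5 stood at 38.8, 49.3 and 103 FPKM against at most 0.074, Dpt at 30.7, 28.3 and 46.6 against at most 0.019, and Col3a1 at 10.8, 19.3 and 55.5 against at most 0.0058. The most abundant members behaved differently from each other. Gsn (gelsolin, an actin-severing protein) stood at 211, 277 and 384 FPKM against 22.6, 141 and 92.3, a difference of -2.06 (SE 0.79, limma adjusted p = 0.79) that was -1.30 without the Krt15-positive replicate 1 library. Dcn (decorin, a matrix proteoglycan) stood at 14, 268 and 457 against 167, 176 and 71.1, a difference of 0.07 (SE 1.14) that turned below 0 with upper-quartile scaling (-0.37), with quantile normalization (-0.12) and with a pseudocount of 5 (-0.0044). The Dcn difference was also -1.34 with library weights, -1.64 without both replicate 1 libraries and 1.44 without both replicate 3 libraries. The list's call held in all 9 settings that left out libraries, with adjusted p between 2.10e-17 and 1.95e-10, including without both replicate 1 libraries (2.48e-14).

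**Figure D3:**
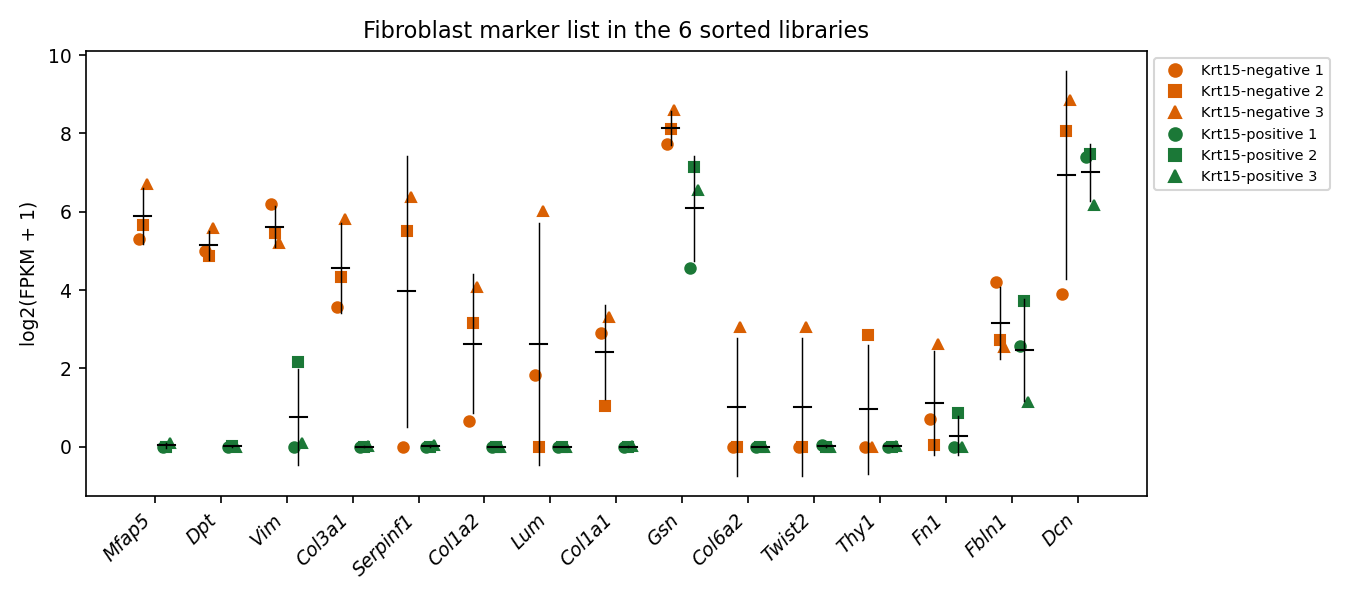
The 15 measured fibroblast markers as log2(FPKM + 1), ordered by their difference, one point per library, colored by group and shaped by replicate number, with horizontal bars at the group mean and vertical bars of 1 SD (n = 3). Mfap5, Dpt, Vim and Col3a1 separate the groups in every library, while Dcn overlaps.

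The extracellular matrix and basement membrane list was also lower (camera adjusted p = 0.0029, and adjusted p = 0.60 with an estimated correlation), with 10 of 19 members below 0. Its members of smallest p were the interstitial collagens Col3a1, Col1a1 (6.45, 1.05 and 8.89 FPKM against at most 0.0069) and Col1a2 (0.58, 7.93 and 15.9 FPKM against 0) and the fibulin gene Fbln2 (6.44, 0.88 and 5.83 FPKM against at most 0.015). Col3a1 was the only member past the test adjusted over the list alone. Without the members that are also fibroblast markers, 13 remained and the list did not pass (camera adjusted p = 0.86, mean difference 0.26). The call also ended without Krt15-negative replicate 1 (0.11), without Krt15-negative replicate 3 (0.16) and without both replicate 1 libraries (0.13, camera adjusted p). The mean difference of the full list, -0.46, was -1.13 with quantile normalization and turned to 0.017 without Krt15-negative replicate 3.

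Immune cell markers were lower as a list, with 13 of 15 members below 0 (camera adjusted p = 1.49e-06, and adjusted p = 0.27 with an estimated correlation). The list mean was 2.86 ± 1.11 in Krt15-negative and 1.56 ± 0.25 in Krt15-positive libraries (exact permutation p = 0.20, SD, n = 3). Tyrobp, a signalling adaptor of myeloid and NK cells, stood at 203, 124 and 31 FPKM against 0, 20.2 and 27.7 (difference -3.46, SE 1.37, limma adjusted p = 0.79, and -1.92 without the Krt15-positive replicate 1 library). Fcer1g, another such adaptor, stood at 0, 107 and 56.9 FPKM against 0.67, 8.97 and 0. Nkg7, a cytotoxic granule gene, was at 459 FPKM in the Krt15-negative replicate 2 library and at most 0.094 elsewhere. Laptm5, a hematopoietic lysosomal gene, stood at 0, 21.3 and 3.91 against 0, 1.86 and 0. The 2 most abundant members had differences above 0, neither past the threshold: Lyz2, lysozyme, stood at 339, 0 and 307 FPKM against 7279, 63.4 and 28.3, and H2-Ab1, an MHC class II gene, at 0, 56.1 and 222 against 35.9, 40.7 and 69.4. The Lyz2 difference of 2.35 turned to -0.43 without the Krt15-negative replicate 2 library, and the H2-Ab1 difference of 1.03 to -1.24 without Krt15-negative replicate 1. The list mean difference was -1.30.

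Genes of respiration and of the ribosome were lower as lists, by amounts that depended on the scaling. In the oxidative phosphorylation list 47 of 63 members were below 0, with a mean difference of -0.23, or -0.14 without the Krt15-negative replicate 3 library (camera adjusted p = 7.05e-14, and adjusted p = 0.19 with an estimated correlation). Cox6c (5017, 1610 and 2654 FPKM against 1750, 1265 and 1222) and the ATP synthase subunit genes Atp5l and Atp5e differed by -0.99 (SE 0.38), -0.90 (SE 0.36) and -0.95 (SE 0.41), and Uqcrb, a complex III subunit gene, by -0.79 (SE 0.32), each with a limma adjusted p of 0.79. Without the Krt15-negative replicate 1 library these differences were -0.57, -0.49, -0.42 and -0.57. In the cytosolic ribosome list 72 of 76 members were below 0, with a mean difference of -0.45 (camera adjusted p = 2.82e-22, and adjusted p = 0.61 with an estimated correlation). Rpl38 stood at 8012, 1731 and 2600 FPKM against 1712, 1673 and 1572, and Rpl35, Rpl32 and Rps19 differed by -0.64 (SE 0.29), -0.59 (SE 0.29) and -0.46 (SE 0.23), none past the threshold. The mean of the list was 11.05 in the Krt15-negative replicate 1 library and between 9.68 and 10.08 in the other 5. Without that library the mean difference was -0.06, Rpl38, Rpl35, Rpl32 and Rps19 differed by -0.36, -0.29, -0.23 and -0.28, and the ribosome call was lost (camera adjusted p = 0.31). Without the Krt15-negative replicate 2 library the mean difference was -0.72. The mean differences of the ribosome and oxidative phosphorylation lists were -0.91 and -0.66 with upper-quartile scaling and -0.31 and -0.09 with median-of-ratios scaling. Quantile normalization ended both calls (camera adjusted p = 0.49 for each), with a mean difference of -0.06 for the ribosome list and 0.0090, turned above 0, for oxidative phosphorylation.

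The G2 and mitosis list was lower by the set test (camera adjusted p = 5.76e-04, and adjusted p = 0.89 with an estimated correlation), with 23 of 34 members below 0 and a mean difference of -0.39. Its means did not separate the groups: 2.02, 3.81 and 3.79 in the Krt15-negative libraries and 2.17, 4.36 and 1.92 in the Krt15-positive ones (exact permutation p = 0.90). Without both replicate 3 libraries the call was lost (camera adjusted p = 0.085) and the mean difference turned to 0.33. It also turned to 0.06 without the Krt15-positive replicate 3 library, and leaving out the other single libraries gave -0.98, -0.08 and -0.12 (Krt15-negative replicates 1 to 3) and -0.06 and -1.20 (Krt15-positive replicates 1 and 2), against -0.89 with quantile normalization. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, stood at 723, 97.2 and 131 FPKM against 53, 131 and 0.25. Ccna2, cyclin A2, stood at 94.6, 11.9 and 22.4 against 2.19, 17.2 and 0.085. Prc1, a spindle midzone gene, differed by -1.86 (SE 1.07) and Birc5, survivin, by -1.13 (SE 0.73), the latter by -1.73 without the Krt15-positive replicate 2 library and -0.70 without replicate 3. The S phase list did not pass (camera adjusted p = 0.86).

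**Figure D4:**
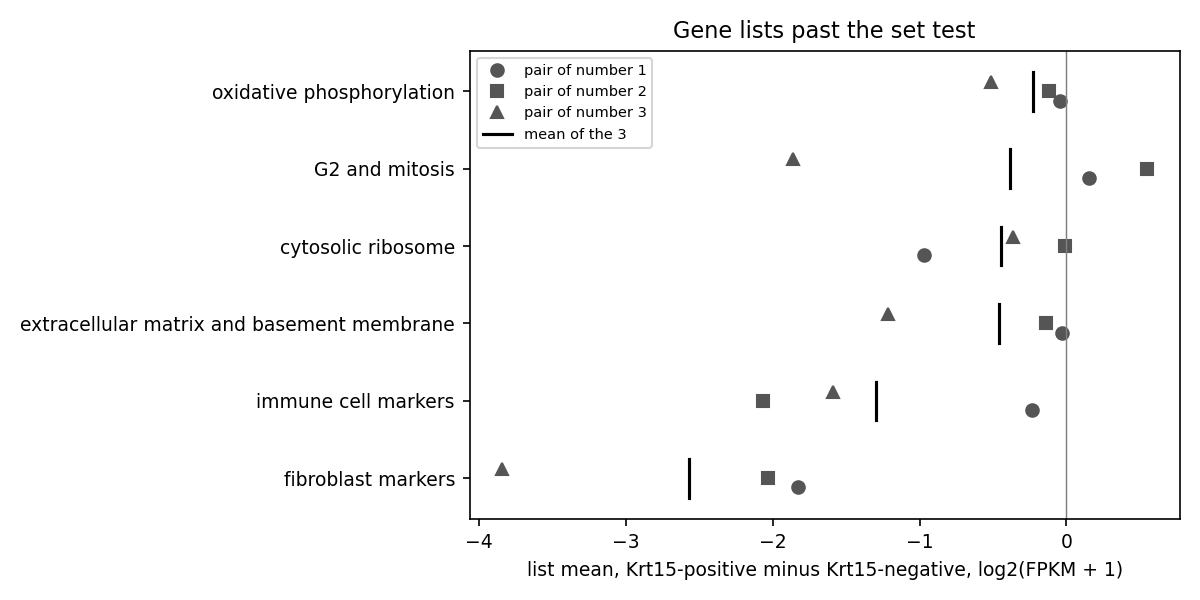
Difference in list mean between the Krt15-positive and the Krt15-negative library of the same replicate number, on the log2(FPKM + 1) scale, for the 6 lists past the set test. Symbols are the 3 replicate numbers and bars their mean, -2.57 for fibroblast markers. Fibroblast markers lie below -1.8 for each number, while G2 and mitosis lies below 0 for number 3 only.

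The other 20 lists did not pass. Closest were cell adhesion and junctions, with 27 of 31 members above 0 (mean difference 1.12, camera adjusted p = 0.053, exact permutation p = 0.10, the smallest possible), and the basal keratinocyte list, with 18 of 19 members above 0 and a mean difference of 1.17 (camera adjusted p = 0.053, exact permutation p = 0.10). Both passed with median-of-ratios scaling (camera adjusted p = 0.044 and 0.033), with quantile normalization (0.021 and 0.020), with library weights (0.0022 and 0.0054) and without the Krt15-negative replicate 1 library (0.0016 and 0.038), and neither with upper-quartile scaling (0.19 and 0.29). Their mean differences fell to 0.58 and 0.60 with quantile normalization and to 0.88 and 0.65 without that library. Leaving out libraries moved the camera adjusted p of cell adhesion and junctions between 3.26e-05 and 0.98 (0.475 without Krt15-negative replicate 3, 0.59 without Krt15-positive replicate 3, and 0.98, with camera's direction turned down, without both). That of the basal keratinocyte list moved between 0.024 and 0.32 (0.27 without Krt15-negative replicate 3, 0.29 without both replicate 3 libraries and 0.32 without Krt15-positive replicate 2). With an estimated correlation the adjusted p was 0.86 and 0.89. Epithelial stem and progenitor markers (14 of 20 above 0, camera adjusted p = 0.93), esophageal suprabasal differentiation (25 of 32 above 0, adjusted p = 0.93), DNA damage repair (22 of 31 above 0, adjusted p = 0.86), p53 targets, Notch and BMP and TGF-beta pathway genes (adjusted p = 0.86 for each) and Wnt pathway genes (19 of 21 above 0, adjusted p = 0.16) did not pass against other genes. Glycolysis and hypoxia response, cell cycle inhibitors and quiescence, autophagy and lysosome, and the sex-linked genes gave the same adjusted p of 0.86. Cholesterol and sterol synthesis stood at 0.93, NRF2 and xenobiotic metabolism and interferon response at 1.00, immediate early and dissociation stress at 0.14 (camera adjusted p), and the responses to glucocorticoid and progesterone receptors at 0.17. Gadd45a, also a p53 target, was the only member of these lists past the test adjusted over the list alone. It stood at 0.030, 0.021 and 0.60 FPKM in Krt15-negative and 32.3, 21 and 32.2 in Krt15-positive libraries, and its limma adjusted p over all genes was 0.79, while it passed with the filter of 10 FPKM in all 3 libraries of a group.

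Markers of the remaining cell types were sparse. Of the endothelial list 2 members were measured, Esam and Flt1, with Flt1 at 13 FPKM in the Krt15-negative replicate 1 library and near 0 elsewhere. Tnni2 and Mylpf of the muscle list, Mbp of the neural and glial list, and Bpgm and Itga2b of the erythroid and platelet list showed no difference past the threshold. With the Hedgehog list, which had 3 measured members, these 5 lists held too few for the set test. The simple and glandular epithelium list did not pass between the groups (camera adjusted p = 0.86). Its mean was 5.44 and 6.56 in the Krt15-negative and Krt15-positive replicate 1 libraries and at most 1.92 in the other 4. Krt19 and Krt7, keratins of simple and ductal epithelia, stood at 190 and 219 FPKM in the Krt15-negative replicate 1 library and at 718 and 78.3 FPKM in the Krt15-positive one, against at most 30.8 and 14.8 FPKM in the others.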

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

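Of the alternatives, quantile normalization, the filter on all 6 libraries, library weights, robust moderation, camera without the trend, the blocked camera with an estimated correlation and the reduced matrix list were chosen after seeing the data. At the estimated depths, 1 fragment on a transcript of 1 kb equals 0.0244 to 0.0371 FPKM, well under the filter of 1 FPKM, yet genes that every cell uses were listed at 0 in some libraries. Genes called numbered 0 in the main comparison, 10 with at least 10 FPKM in all 3 libraries of a group (5 in each direction; that filter favors genes absent from one group) and 8 with library weights (all lower; the weights were 0.23 for Krt15-negative replicate 1 and 3.2 for replicate 3). Leaving out libraries gave 0 to 1, the 1 without Krt15-negative replicate 2. The replicate numbers are shared by both groups, and so is a prefix of the sample names for each number, which the labels do not explain. Xist, Mir692-2b and the airway gene Scgb3a2 also followed the numbers. Libraries of the same number thus shared traits across the groups, which the main fit without a block does not take up. The deviations of same-numbered libraries correlated at 0.13, 0.17 and 0.0089, and the numbers were not taken to pair the samples. This check cannot exclude a pairing, because the deviations of 3 libraries within a group add up to 0. Krt15-negative replicate 3 correlated best with Krt15-positive replicate 2 (0.029), so not every sample was closest to its own number. With the replicate block the SE of Krt15 expression was 0.19 against 0.48, 0 genes passed, and 9 lists passed against 6, the added ones being basal keratinocyte (adjusted p = 0.035), cell adhesion and junctions (0.028) and immediate early and dissociation stress (0.021). Lists called fell to 0 with an estimated correlation, 0 with fry and 0 with the block and an estimated correlation, and ranged from 5 to 9 when libraries were left out. With fry the adjusted p were 0.78 for G2 and mitosis, 0.63 for ribosome, 0.31 for oxidative phosphorylation, 0.60 for matrix, 0.21 for fibroblast and 0.47 for immune markers; in either direction fry gave 0.0079 for fibroblast markers and 0.029 for matrix. With an estimated correlation they were 0.89, 0.61, 0.19, 0.60, 0.19 and 0.27, and with the block as well 0.82 for G2 and mitosis and 0.56 for the other 5. Quantile normalization gave 0.49 for ribosome and 0.49 for oxidative phosphorylation, and the matrix list without fibroblast markers 0.86. Leaving out libraries moved the adjusted p of the ribosome list between 5.62e-43 and 0.31, G2 and mitosis between 9.94e-08 and 0.085 and matrix between 9.15e-04 and 0.16 (lost without Krt15-negative replicate 1 at 0.11, without Krt15-negative replicate 3 and without both replicate 1 libraries at 0.13). With 1 FPKM required in all 6 libraries the fibroblast, matrix and immune lists kept too few members to test. Upper-quartile scaling turned Krt15 to -0.29, Krt5 to -0.41, Krt14 to -0.45 and Dcn to -0.37. It divided the values of Krt15-negative replicate 1 by 0.36 and those of the other libraries by 0.96 to 1.52. This lowers the difference of all abundant genes by a like amount. A pseudocount of 5 turned Dcn to -0.0044, and quantile normalization turned Dcn to -0.12 and Esam to -0.12. Library weights turned Dcn to -1.34, Esam to -1.45, H2-Ab1 to -1.55, Tnni2 to -0.20, Mylpf to -0.074, Bpgm to -0.73, Itga2b to 0.23 and Krt7 to 0.86. Leaving out libraries gave ranges across 0 for Krt15 (-0.41 to 0.60), Krt5 (-0.52 to 0.48), Krt14 (-0.37 to 0.48), Dcn (-1.64 to 1.44), Esam (-1.27 to 1.75), Lyz2 (-0.43 to 5.22), H2-Ab1 (-1.24 to 2.66), Tnni2 (-0.10 to 3.44), Mylpf (-1.77 to 2.03), Bpgm (-0.093 to 1.40), Itga2b (-1.47 to 0.27), Krt19 (-3.87 to 0.94) and Krt7 (-2.37 to 1.79). Apart from the changes with upper-quartile scaling, the cause was not tested for these changes. Of the other values of named genes, 518 under other settings and 397 with libraries left out kept their direction and side of the threshold. The planned count models (DESeq2, voom and the like) were not run, since the values are not counts.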

Other observations

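The test of whole-lung tissue and those of low complexity and depth of the Krt15-negative replicate 1 library were chosen only after the result was seen. Genes named in this part were picked after their values were seen.

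Both replicate 1 libraries carried abundant transcripts of some genes known from airway secretory cells that were far lower in the other 4. Scgb3a2, a secretoglobin of bronchial club cells, was the most abundant gene of the Krt15-negative replicate 1 library at 53450 FPKM and stood at 49560 FPKM in the Krt15-positive one, against at most 8.67 elsewhere. Scgb1a1, the club cell secretory protein, was the most abundant gene of the Krt15-positive replicate 1 library at 88100 FPKM, with 18920 in its Krt15-negative counterpart and at most 13.3 elsewhere. Bpifa1, an airway antimicrobial protein, stood at 11770 FPKM in the Krt15-negative replicate 1 library and was listed at 0 in the Krt15-positive one. Reg3g, a secreted lectin, reached 1517 FPKM in the Krt15-positive replicate 1 library and at most 0.052 in the others. Of the club cell genes Cyp2f2 and Cbr2, the former did not follow this pattern. It stood at 263 FPKM in the Krt15-negative replicate 1 library, 3845 in the Krt15-positive one and 566 to 988 in the other 4. Cbr2 was higher in both replicate 1 libraries, at 2272 and 8499 FPKM, against 838 to 1019 in the other 4, a smaller gap. The simple epithelial keratins Krt8 and Krt18 stood at 37.6 and 49.1 FPKM in the Krt15-negative replicate 1 library and 231 and 559 in the Krt15-positive one, against at most 0.11 and 0.025 elsewhere.

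A candidate explanation is airway epithelium, or its RNA, in the replicate 1 samples, tested on a second list of airway genes written before its values were looked at. The median difference of its 22 measured members (Foxa1, Muc1 and Hopx are in other lists too, and 4 reached 1 FPKM in all 4 other libraries), replicate 1 minus the others, was 3.05 on the log2 scale, against at most 2.40 for any other of the 15 pairs of libraries, but it came mostly from the Krt15-positive library (5.89 alone, with all 22 members at 1 FPKM or more), and every pair holding it gave 2.07 or more. Of the list's 31 genes, 22 passed the filter of a mean of 1 FPKM, and 13 of them reached 1 FPKM in none of the other 4 libraries. The Krt15-positive replicate 1 library could thus admit members by itself, so 5.89, 3.05 and the count of 22 were partly set by the filter. The Krt15-negative replicate 1 library gave 0.74, with 11 members below 1 FPKM (Muc1 at 0 against 74.7 in the Krt15-positive one) and 6 that reached 1 FPKM in none of the 4 others, among them Ltf (lactoferrin, 195 FPKM), so for that library the list leaves the explanation open. The CD29 and GFP gates could each remove such cells, neither effect was tested, and the GFP-positive library held the higher levels of Scgb1a1 and of Ltf (1869 FPKM). Whole lung stays open: of 14 alveolar genes 2 (14.3%, Sftpa1 and Sftpd, the latter also made by club cells) reached 1 FPKM in both libraries, 3 in the Krt15-negative one (with Sftpb at 1.70 FPKM) and 4 (28.6%) in the Krt15-positive one (with Aqp5 at 224 and Sftpc at 7.90), and a listed 0, as for Ager throughout, can be a failed estimate.

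Fibroblast markers averaged 1.11 on the log2 scale in the Krt15-positive libraries and 3.68 in the Krt15-negative ones. None of 10000 random lists matched on expression had a mean as low (0 lists, the lowest at -0.62 against -2.57), and their median was 0.47. The fall of the list thus ran against genes of like expression. Random members were drawn one by one and do not vary together as markers of one cell type can. The count of 0 therefore does not measure how often such a list would fall by chance. On average the Krt15-positive libraries held more genes at 1 FPKM or more (8244 against 6029). The test therefore could not have shown a general loss of genes in them. Fibroblasts in the GFP-negative sort are a candidate explanation, since the gate named in the labels uses CD29, which fibroblasts also carry, and a Krt15-driven Cre would leave them GFP-negative. In a second fibroblast list of 42 genes, 22 passed the filter of a mean of 1 FPKM. That filter can admit a gene through 1 library alone, which favors a difference. Of the 22 members, 19 were below 0 with a median of -1.35. Those that separated the groups were 5 (22.7%, against 2.44% of all tested genes and 5% by chance in that direction), fewer than the share set beforehand. Fibroblasts in the sort therefore stay open as an explanation. Expression of these genes by Krt15-negative basal cells was not tested and stays open too.

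More genes were higher than lower in Krt15-positive cells at an unadjusted p below 0.05 (81.1% of 370). Without the Krt15-negative replicate 1 library the share was 52.5%, and without both replicate 1 libraries 52.9%. Without both replicate 2 libraries, which keeps the Krt15-negative replicate 1 library, it was 37.5% (48 higher and 80 lower). Leaving out other libraries gave 66.2% (without Krt15-negative replicate 2) to 97.6% (without both replicate 3 libraries). Library weights gave 58.7% and the filter of 10 FPKM 63.2%. Genes at 1 FPKM or more in all 6 libraries gave 35.3% (18 higher and 33 lower). The median difference of all genes, 0.63, was 0.03 without the Krt15-negative replicate 1 library and 0.80 without both replicate 2 libraries. Whether the low number of genes in the Krt15-negative replicate 1 library is the source of the share stays open. Krt15-negative replicate 2 listed 15111 genes at 0, the most after replicate 1 (17605), and its part in the share stays open too. The estimated depth of the Krt15-negative replicate 1 library, 28 M fragments against 26.9 M of the Krt15-positive replicate 1 library, argues against shallow sequencing. Median-of-ratios scaling, which raised the median difference to 0.73, gave a share of 88.4%, and upper-quartile scaling gave 77.3%. Neither of these scaling factors per library removed the excess, which leaves other factors open. Quantile normalization, which gives all libraries one distribution and so also evens out the number of detected genes, gave 40.5%, and fewer captured molecules stay open, since cell numbers were not used here.

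Of the 10 splits of the 6 libraries, the real one gave a mean difference of fibroblast markers of 2.57 in size and the highest other 1.65, so 1 split was as large. The real split called 0 genes, the highest other 1, and all 10 splits gave at least as many. It called 6 lists, the others 3 to 8, and 3 splits gave at least as many. The 10 splits are too few for a share under 0.05 in any of these. At an unadjusted p below 0.05 the real split gave 370 genes, and 4 of the 9 others gave more, up to 582.

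Xist stood at 6.13 and 17.6 FPKM in both replicate 3 libraries and at most 0.0073 in the other 4, where Eif2s3y stood between 6.29 and 26.3. In the replicate 3 libraries Eif2s3y, a Y-linked gene, stood at 0.015 and 0.019 FPKM. Ddx3y, another Y-linked gene, stood at 0.0073 FPKM in the Krt15-negative replicate 1 library and at 9.14 in the Krt15-positive one. Mir692-2b was at 8627 and 6888 FPKM in the replicate 3 libraries and at most 106 elsewhere.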
